A study of Homo sapiens with 9 samples.

How the data were processed

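Messenger RNA was sequenced from Jurkat Clone E6-1 cells, an established human leukaemic T-cell line, in 9 libraries that form 3 groups of 3: non-activated cells (0 h), and cells activated for 5 h or 12 h. Per the labels' protocols, activation used plates coated with anti-CD3 antibody at 10 µg/mL and anti-CD28 antibody added to the medium at 5 µg/mL. RNA was purified with a Direct-zol kit and libraries were made from total RNA with a RealSeq kit, per the labels' protocols. The labels call the 3 libraries of a group biological replicates and give no batch or date. They do not say whether these came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Ribosome profiling and small RNA data of the same study were not analysed here.

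The deposited count table holds whole-number counts per Ensembl gene, which the authors made without a normalization that the values show. The submitters' processing notes name cutadapt, RSEM and DESeq2 and the genome build GRCh38.p13, with no role, order or version. The annotation release, the aligner and the use of strand are not given in the sources used here. RSEM gives estimated counts, so the deposited counts may be rounded estimates. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and counts of near-identical genes such as XCL1 and XCL2 are uncertain. The authors also deposited log2 expression values. A test on the file showed that each value equals log2 of the count divided by 1 factor per library, plus 1, and that the table lists the 12692 genes with a count above 0 in all 9 libraries. It leaves out 4005 genes that have counts, with up to 14710 counts in total for 1 gene, so the log2 values were used only in an alternative.

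The count table has 19569 genes, of which 16697 have any count and 19543 matched the gene symbol table. Of its genes, 19500 are in GENCODE release 29 (GRCh38), which gave the coordinates, and 19450 of these are protein-coding. Each coordinate is 1-based. The 18 copies of pseudoautosomal genes on chromosome Y hold 42931 counts. Library totals ran from 4222258 to 9359187 counts. A count of 0 allows up to 3 counts, which over the 0 h group is 0.132 CPM (counts scaled to 1e6 per library), and lower bounds on a fold were computed against that floor. Intervals and floors cover counting error only. Chi-square over degrees of freedom between replicates of a group was 2.95 to 9.39, so no pair agreed within sampling noise and each library counted as 1 replicate.

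Genes were tested with edgeR 4.0.16 in R 4.3.3. The 9 libraries entered 1 quasi-likelihood fit with a coefficient per group, TMM normalization and the filterByExpr filter, which left 12036 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.0887. CPM values use the TMM-scaled library sizes. Adjusted p-values of genes in the report come from this edgeR test unless another test is named, standard errors (SE) are on the log2 scale, and means are ± SD with n = 3. On counts simulated from the 9 libraries for 5 h against 0 h (11880 genes), the test recovered 76% of 50 genes changed 1.5-fold, 96% of 50 changed 2-fold, 100% of 50 changed 4-fold and 88% of 50 lowered to 0.5 of their level. It made 14 false calls among 11680 unchanged genes, and none among 11880 for simulated 12 h against 0 h. The simulated genes were independent and few of them changed. These counts therefore cannot show how often genes are called falsely when many genes change, as in the data.

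Before the data were examined, 29 gene lists with 927 members were fixed, of which 895 members are in the table. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moves relative to the other genes. Camera with an estimated correlation in place of the preset is given beside each call. A call lost there does not by itself show that the members are correlated. At 12 h against 0 h, negative-feedback regulators had an estimated correlation of -0.0029, below the preset. Their camera adjusted p still went from 0.02 to 0.0878. Fry, which asks whether a list's members move on balance in 1 direction, was an alternative. In the simulated 5 h comparison, camera called the raised set and 0 of 20 unchanged sets. These sets held random genes simulated independently, so they cannot show how often lists of correlated genes are called falsely. The estimated correlation of ribosomal proteins at 5 h was 0.62.

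For miRNA seed families, the longest annotated 3′ UTR of 11952 tested genes was searched for sites, and 84 genes without an annotated 3′ UTR were not searched. In each library, the log2 CPM of each gene minus its mean over the 9 libraries was regressed on the presence of a 7mer-m8 or 8mer site, the log2 UTR length and the A+U share. The site coefficient of each of 32 families or motifs in each library was then tested with limma between groups, with Benjamini-Hochberg adjustment over the 32. These comprise 27 miRNA families, 3 miRNAs of other tissues as controls and 2 other motifs. The limma intervals had the same width for every family, from miR-210 (395 genes with a site) to the AU-rich element (4246). The intervals and p-values thus rest on a spread pooled over families, and do not measure the spread of a single family between libraries. In simulated data with a difference of -0.1 for miR-155 at 5 h, the recovered value was -0.102 and 0 other families were called. Genes were simulated independently and only those with a miR-155 site changed. The simulation therefore cannot show how often a family is called falsely in the data. As a background, 1080 random 7-mers with a number of site-bearing genes within 15% of that of a family, 40 per family, went through the same steps.

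Genes were named by a rule fixed beforehand. For each comparison it takes the 8 highest and 8 lowest fold changes among called genes with at least 5 CPM in the higher group and CPM ranges that do not overlap. It also takes up to 2 called members per list and direction, the activation genes IL2, CD69, EGR1, EGR2, NR4A1 and IL2RA, and the miRNA pathway genes DICER1, DROSHA and AGO2. The miRNA host transcripts MIR17HG and MIR155HG and several other listed genes were not analysed here. Genes named outside this rule were chosen after their values were seen, and this is said where they appear. The results of a few genes are not reported here.

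The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma on the deposited log2 values, no low-count filter, a stricter filter of 1 CPM in 3 libraries with 100 counts in total, and a fit of only the groups compared. Further alternatives were the replicate number as a block, a test against a fold of 1.5, 8mer sites only, genes of at least 10 CPM, and leaving out each library in turn. Of these, no setting shifted the median log2 fold change of all genes by more than 0.0014 where the scaling changed. These scalings all centre the typical gene, so a small shift is built in and does not test a change in mRNA per cell. Fold changes here are relative to the other mRNAs of a library.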

Results

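Messenger RNA was measured in Jurkat Clone E6-1 cells, a human leukaemic T-cell line widely used to study T-cell receptor signalling. The 9 libraries were 3 of non-activated cells (0 h), 3 of cells activated for 5 h through CD3 and CD28, and 3 of cells activated for 12 h. The study is concerned with how miRNAs repress translation or degrade mRNA during T-cell activation, and the mRNA libraries show which transcripts changed in abundance. Total counts were 7496782, 6270320 and 7805119 in the 0 h libraries, 6936240, 7615112 and 6552491 at 5 h, and 4222258, 9359187 and 6891208 at 12 h. In a principal component analysis, the first component (60.3% of the variance) placed the 0 h libraries between -55.07 and -54.63 and the activated libraries between 20.48 and 35.35. The second (18.2%) placed the 5 h libraries between 21.91 and 28.53 and the 12 h libraries between -29.43 and -26.49.

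The comparison of 5 h with 0 h asked how the mRNA population differed early after activation. The 9 libraries include no non-activated cells kept for 5 h or 12 h. In every comparison with 0 h, activation therefore cannot be told apart from time in culture or handling. IL2RA, the inducible alpha chain of the interleukin-2 receptor (chromosome 10, 6010689 to 6062370, GRCh38), had no count in any 0 h library and 339 ± 7.60 CPM at 5 h (SD, n = 3), at least 2561-fold higher. IL2, the T-cell growth factor (chromosome 4, 122451470 to 122456725), rose from 0.0905 ± 0.0796 to 260.1 ± 38.1 CPM. With 2 counts at 0 h, that ratio was 2955 (95% counting interval 818 to 24409). The chemokine gene XCL1 rose from 0.122 ± 0.211 to 482 ± 27.4 CPM, a ratio of 3661 (1252 to 17757). XCL2 rose from 0.163 ± 0.282 to 394 ± 15.6 CPM, although reads of this near-identical pair may be split wrongly. The cytokine genes IL3 and CSF2, absent at 0 h, reached 48.5 ± 3.75 and 47.8 ± 3.38 CPM, at least 366-fold and 362-fold higher. The chemokine gene CCL4L2, a copy of CCL4, was at least 154-fold higher, and the matrix metalloproteinase gene MMP10 at least 104-fold higher.

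The genes that fell most at 5 h included KLF2, a transcription factor of quiescent T cells, which went from 40.7 ± 0.147 to 2.49 ± 0.224 CPM (log2 fold change -4.02 ± 0.18 SE, edgeR adjusted p = 8.07e-14, n = 3). PTGDR2, a prostaglandin D2 receptor, fell from 25.9 ± 2.49 to 1.82 ± 0.808 CPM (log2 -3.83). The Rap1 GTPase-activating protein genes RAP1GAP2 (log2 -3.39) and RAP1GAP (log2 -3.00) fell from 60.4 ± 6.72 to 5.72 ± 1.40 CPM and from 70.4 ± 1.98 to 8.72 ± 2.45 CPM. CDKN2D, a cyclin-dependent kinase inhibitor, fell from 36.4 ± 5.24 to 3.69 ± 0.531 CPM (log2 -3.29). TRARG1 (log2 -4.67) and the tubulin gene TUBB3 (log2 -3.13) also fell, from 5.41 and 9.13 CPM at 0 h.

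Among the genes taken as a check of activation, the surface receptor CD69 rose from 73.3 ± 7.76 to 865 ± 49.2 CPM (log2 3.56 ± 0.11, edgeR adjusted p = 1.97e-16). The zinc-finger factor EGR1 rose from 13.6 ± 1.32 to 1173 ± 25.9 CPM (log2 6.43) and EGR2 from 0.401 ± 0.140 to 72.6 ± 1.75 CPM (log2 7.45). The nuclear receptor NR4A1 rose from 9.19 ± 0.512 to 1426 ± 67.6 CPM (log2 7.28). All 3 groups for these and other genes are in the plot of CPM by time.

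**Figure D1:**
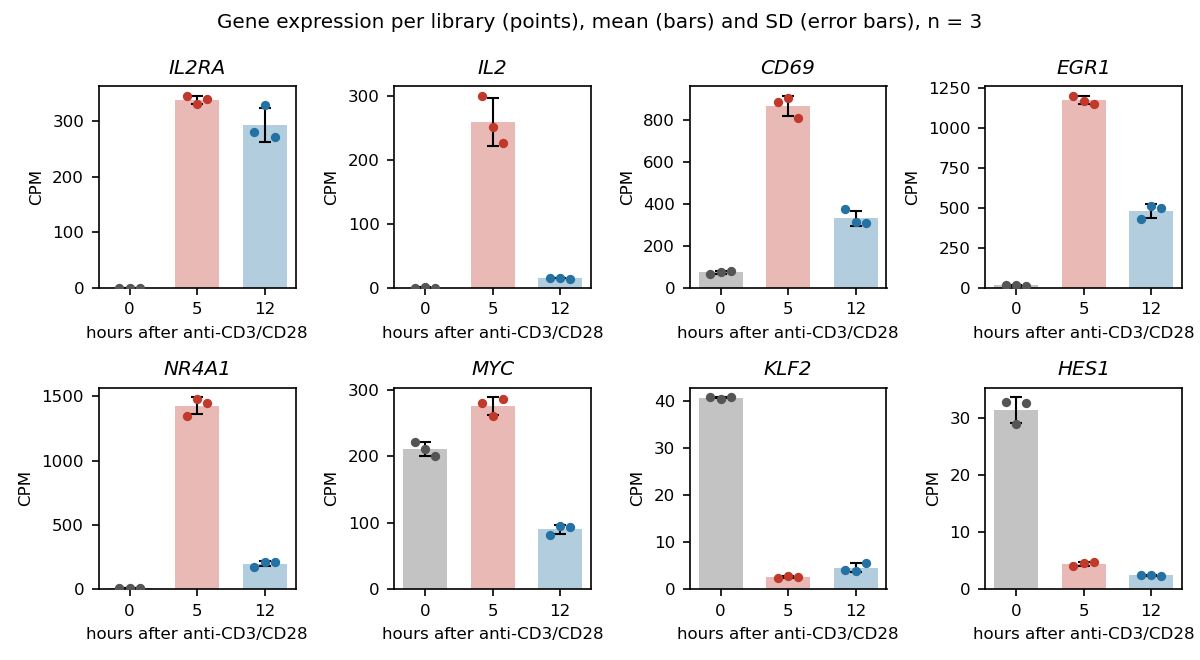
Mean CPM (bars), SD (error bars) and the 3 libraries of each group (points) at 0, 5 and 12 h for IL2RA, IL2, CD69, EGR1, NR4A1, MYC, KLF2 and HES1. IL2RA was at 339 CPM at 5 h and 294 CPM at 12 h, while IL2 went from 260.1 to 15.1 CPM.

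In the edgeR test, 3001 genes were higher and 2984 lower at 5 h among 12036 tested, 49.7% of them, with 663 higher and 774 lower by at least 2-fold. Of the 26 lists with a set test, camera called 13. With an estimated correlation, 5 held: immediate-early transcription factors, NF-κB targets, negative-feedback regulators, DNA replication, and Notch pathway and T-cell leukaemia factors. Counts of list members below are those called over all genes tested, and the count adjusted over the list alone was the same except where both are given.

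Transcription factors and signalling lists rose at 5 h. Of 23 immediate-early transcription factors, 20 rose and 0 fell (adjusted over the list alone, 20 and 1; camera adjusted p = 2.15e-13, and adjusted p = 0.0328 with an estimated correlation). NR4A3 rose from 1.19 ± 0.160 to 635 ± 10.5 CPM (log2 9.04). Of 22 NF-κB targets, 19 rose and 0 fell (camera adjusted p = 3.19e-14, and adjusted p = 0.0135 with an estimated correlation), among them the anti-apoptotic gene BCL2A1 (0.453 to 113 CPM, log2 7.94) and the NF-κB subunit RELB (2.09 to 94.0 CPM, log2 5.44). Of 32 negative-feedback regulators, 18 rose and 5 fell (camera adjusted p = 1.00e-05, and adjusted p = 0.0229 with an estimated correlation). The MAP kinase phosphatases DUSP4 (0.490 to 147 CPM, log2 8.20) and DUSP5 (log2 6.38) rose, while the phosphatase UBASH3A (log2 -1.54) and the adaptor PAG1 (log2 -1.14) fell.

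Secreted and surface molecules of activated T cells also rose at 5 h. Of 19 cytokines and chemokines, 15 rose and 2 fell (adjusted over the list alone, 15 and 3; camera adjusted p = 1.54e-07, but adjusted p = 0.0971 with an estimated correlation). The list median was 3.85 on the log2 scale, and the same with the 3 genes without a 0 h count at their bound. FLT3LG (10.7 to 3.02 CPM, log2 -1.81) and TGFB1 (108 to 72.8 CPM, log2 -0.57) fell. Of 26 activation receptors and ligands, 24 rose and 1, CD38 (log2 -0.46), fell (camera adjusted p = 3.19e-14, but adjusted p = 0.0801 with an estimated correlation). The adhesion receptor CRTAM rose to 205 ± 3.22 CPM (log2 7.26). Of 12 inhibitory receptors and exhaustion factors, 7 rose and 3 fell, with no call for the list (camera adjusted p = 0.157). PDCD1, which encodes PD-1, rose from 2.47 ± 0.600 to 30.8 ± 9.96 CPM (log2 3.64), and the collagen receptor LAIR1 fell from 188 ± 10.6 to 35.7 ± 2.32 CPM (log2 -2.39).

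The T-cell receptor and quiescence lists went both ways at 5 h, while the Notch pathway and T-cell leukaemia list fell. Of 36 genes of the T-cell receptor complex and proximal signalling, 12 rose and 14 fell (adjusted over the list alone, 14 and 14; camera adjusted p = 0.97), with a median log2 fold change of -0.05, a mean of 0.01 and a set test in the negative direction. The adaptor LCP2 rose from 210.4 to 924 CPM (log2 2.14), while the adaptor GRAP2 fell from 149 to 41.9 CPM (log2 -1.83). Of 28 quiescence and homing genes, 7 rose and 15 fell (adjusted over the list alone, 7 and 16; camera adjusted p = 0.157). The repressor BACH2 rose from 51.3 ± 4.82 to 773 ± 48.9 CPM (log2 3.92) and IL7R from 20.1 to 73.8 CPM (log2 1.87). Of 21 Notch pathway and T-cell leukaemia factors, 3 rose and 15 fell (camera adjusted p = 3.10e-04, and adjusted p = 0.0328 with an estimated correlation). NOTCH1 fell from 338 ± 29.5 to 70.8 ± 9.10 CPM (log2 -2.25) and its target HES1 from 31.4 ± 2.23 to 4.45 ± 0.344 CPM (log2 -2.82), while RUNX3 rose from 20.3 to 132 CPM (log2 2.71).

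Lists of ribosomes and translation, of the unfolded protein response and of interferon-stimulated genes rose at 5 h by smaller amounts, and none of these calls held with an estimated correlation. Of 56 ribosome biogenesis genes, 38 rose and 1, NOP56 (log2 -0.39), fell (adjusted over the list alone, 39 and 1; camera adjusted p = 7.16e-09, but adjusted p = 0.225 with an estimated correlation). PPAN rose from 64.0 to 189.8 CPM (log2 1.57). Of 77 cytosolic ribosomal proteins, 33 rose and 0 fell, with a median log2 fold change of 0.21 (camera adjusted p = 3.40e-05, but adjusted p = 0.565 with an estimated correlation). Of 48 translation factors, 29 rose and 2 fell (adjusted over the list alone, 30 and 2; camera adjusted p = 7.39e-05, but adjusted p = 0.26 with an estimated correlation), among them the poly(A)-binding protein gene PABPC1 (1189 to 1969 CPM, log2 0.73). Of 31 unfolded protein response genes, 18 rose and 5 fell (camera adjusted p = 4.05e-04, but adjusted p = 0.35 with an estimated correlation). The endoplasmic reticulum chaperones HSP90B1 (760.5 to 2745 CPM, log2 1.85) and HSPA5 (611 to 1933 CPM, log2 1.66) rose. Of 36 interferon-stimulated genes, 14 rose and 9 fell (adjusted over the list alone, 15 and 9; camera adjusted p = 0.023, but adjusted p = 0.111 with an estimated correlation). The guanylate-binding protein gene GBP2 rose from 0.986 to 81.2 CPM (log2 6.30), while RSAD2 (log2 -1.46) fell.

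Cell-cycle lists fell at 5 h. Of 46 DNA replication genes, 39 fell and 1, the cyclin gene CCND2 (2.32 to 7.06 CPM, log2 1.59), rose (adjusted over the list alone, 40 and 1; camera adjusted p = 1.33e-15, and adjusted p = 0.0285 with an estimated correlation). The list median was -0.71. CCND3 fell from 423 ± 16.9 to 117 ± 4.08 CPM (log2 -1.85) and E2F2 from 119.6 to 33.3 CPM (log2 -1.84). Of 46 mitosis genes, 30 fell and 1, KIF20B (log2 0.70), rose (adjusted over the list alone, 31 and 1; camera adjusted p = 3.89e-06, but adjusted p = 0.24 with an estimated correlation), with a median of -0.34. GTSE1 fell from 86.3 to 42.6 CPM (log2 -1.02) and CDC20 from 94.1 to 48.7 CPM (log2 -0.95).

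The other lists were not called by camera at 5 h. Amino-acid supply and tRNA charging had 18 members higher and 10 lower of 38 (adjusted over the list alone, 19 and 11; camera adjusted p = 0.0929). The amino-acid transporter SLC7A5 rose from 602 ± 64.7 to 3234 ± 311 CPM (log2 2.43). Cholesterol synthesis had 8 higher and 7 lower of 23 (camera adjusted p = 0.51), and glycolysis 7 and 8 of 24 (camera adjusted p = 0.97, with a median of 0.07, a mean of -0.07 and a negative direction in the set test). The pyruvate kinase gene PKM rose from 882 to 1888 CPM (log2 1.10) and the glucose transporter gene SLC2A1 fell from 118 to 39.4 CPM (log2 -1.58). Heat shock proteins had 4 higher and 6 lower of 22 (camera adjusted p = 0.69), and replication-dependent histones 0 and 4 of 6 (camera adjusted p = 0.142). Of 7 mitochondrially encoded genes, 2 passed over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.358). These were MT-CO1 (log2 0.36, adjusted p = 0.0395) and MT-ATP8 (log2 0.39, adjusted p = 0.0417). Both calls were lost without 0 h replicate 1 (MT-CO1 0.34, MT-ATP8 0.42), 0 h replicate 2 (0.31 and 0.29) or 5 h replicate 1 (0.24 and 0.15), and that of MT-CO1 also without 5 h replicate 2 (0.35). Both were also lost in the DESeq2 Wald test (adjusted p = 0.132 for MT-CO1 and 0.195 for MT-ATP8) and in limma on the deposited log2 values (0.13 and 0.0564).

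The comparison of 12 h with 0 h asked which changes stood at the later time. IL2RA was at 294 ± 30.7 CPM, at least 2271-fold above 0 h. XCL1 was at 233 ± 34.2 CPM, a ratio of 1824 (95% counting interval 624 to 8847), and XCL2 at 147 ± 19.5 CPM. GZMB, which encodes the cytotoxic protease granzyme B, was at 58.9 ± 7.12 CPM, a ratio of 671 (185 to 5551), and the adhesion gene VCAM1 at 10.2 ± 2.96 CPM, a ratio of 221 (39.2 to 8780). MMP10, ENTPD2 and IL3 were at least 45.7-fold, 41.2-fold and 39.7-fold above 0 h. IL2 stood at 15.1 ± 0.740 CPM, a ratio of 171 (47.0 to 1421). The largest falls were in MYT1 (log2 -4.11), RAP1GAP2 (60.4 to 4.08 CPM, log2 -3.97), PTGDR2 (log2 -3.69), HES1 (31.4 to 2.44 CPM, log2 -3.68) and the chemokine receptor CXCR3 (17.1 to 1.29 CPM, log2 -3.66). ANKEF1 (log2 -3.37), KLF2 (4.53 ± 0.964 CPM, log2 -3.17) and PI16 (110 to 12.6 CPM, log2 -3.15) followed.

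The activation genes stayed above 0 h at 12 h: CD69 at 331 ± 35.8 CPM (log2 2.17), EGR1 at 479 ± 43.4 CPM (log2 5.14), EGR2 at 16.3 ± 1.93 CPM (log2 5.28) and NR4A1 at 198 ± 21.9 CPM (log2 4.44). MYC, a growth-promoting transcription factor, was below 0 h, at 90.3 ± 7.01 against 211 ± 10.8 CPM (log2 -1.22 ± 0.09 SE, edgeR adjusted p = 7.10e-10). The edgeR test found 3160 genes higher and 2985 lower at 12 h, 51.1% of those tested, with 702 and 738 by at least 2-fold. Camera called 11 of 26 lists, and 4 held with an estimated correlation: NF-κB targets, DNA replication, cholesterol synthesis, and Notch pathway and T-cell leukaemia factors.

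Cholesterol synthesis and ribosomal protein genes rose at 12 h. Of 23 cholesterol synthesis genes, 19 rose and 2 fell, with a median log2 fold change of 1.06 (camera adjusted p = 3.70e-10, and adjusted p = 0.0475 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 142 ± 14.9 to 680 CPM (log2 2.26) and MSMO1 to 252 CPM from 56.2 (log2 2.16), while LSS was lower, at 61.5 against 99.2 CPM. All 77 cytosolic ribosomal protein genes tested rose and 0 fell, with a median of 0.51 (camera adjusted p = 3.73e-17, but adjusted p = 0.346 with an estimated correlation). RPL12 rose from 314 to 562 CPM (log2 0.84) and RPL3 from 658 to 1132 CPM (log2 0.78). Ribosomal protein genes took 4.28% ± 0.16 of all counts at 0 h, 4.65% ± 0.26 at 5 h and 5.72% ± 0.59 at 12 h (n = 3). An exact two-sided permutation test of that share, 12 h against 0 h, gave p = 0.1, the smallest that 3 against 3 libraries allow.

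DNA replication genes were lower at 12 h, with 43 of 46 lower and 1 higher and a median of -0.95 (camera adjusted p = 3.70e-20, and adjusted p = 0.0227 with an estimated correlation). CCNE2 fell from 44.8 to 12.7 CPM (log2 -1.83) and GINS2 from 78.7 to 24.6 CPM (log2 -1.67). Mitosis genes were not called, with 13 higher and 10 lower of 46 and a median of 0.10 (camera adjusted p = 0.624). Notch pathway and T-cell leukaemia factors had 3 higher and 15 lower of 21 (camera adjusted p = 3.42e-04, and adjusted p = 0.0449 with an estimated correlation). Replication-dependent histones had 1 higher and 2 lower of 6 (camera adjusted p = 0.8).

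Camera called these lists higher at 12 h. NF-κB targets had 18 higher and 0 lower of 22 (camera adjusted p = 3.11e-10, and adjusted p = 0.0227 with an estimated correlation), with BCL2A1 at 48.9 CPM (log2 6.73) and RELB at 56.8 CPM (log2 4.73). Immediate-early factors had 13 higher and 2 lower of 23 (camera adjusted p = 7.05e-05, but adjusted p = 0.168 with an estimated correlation). Activation receptors and ligands had 21 higher and 2 lower of 26 (camera adjusted p = 1.90e-09, but adjusted p = 0.138 with an estimated correlation). Cytokines and chemokines had 10 higher and 4 lower of 19 (adjusted over the list alone, 11 and 5; camera adjusted p = 0.00507, but adjusted p = 0.346 with an estimated correlation), with a median of 2.46, or 1.88 with the genes at 0 set at their bound. Negative-feedback regulators had 17 higher and 8 lower of 32 (camera adjusted p = 0.02, but adjusted p = 0.0878 with an estimated correlation). Interferon-stimulated genes had 19 higher and 6 lower of 36 (camera adjusted p = 0.00222, but adjusted p = 0.0587 with an estimated correlation), with GBP2 at 91.9 CPM (log2 6.49). Amino-acid supply and tRNA charging had 22 higher and 6 lower of 38 (camera adjusted p = 0.00956, but adjusted p = 0.0735 with an estimated correlation), among them the asparagine synthetase gene ASNS (39.4 to 85.4 CPM).

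The remaining lists were not called by camera at 12 h. T-cell receptor genes had 11 higher and 11 lower of 36 (adjusted over the list alone, 13 and 12; adjusted p = 0.8), with CD3G down from 744 ± 46.3 to 337 ± 30.3 CPM (log2 -1.14). Quiescence and homing genes had 6 and 11 of 28 (adjusted over the list alone, 7 and 11; adjusted p = 0.47), inhibitory receptors 7 and 3 of 12 (adjusted p = 0.275), and translation factors 23 and 8 of 48 (adjusted over the list alone, 24 and 8; adjusted p = 0.145). Ribosome biogenesis had 13 higher and 12 lower of 56 (adjusted p = 0.943, with a median of -0.01, a mean of 0.01 and a negative direction in the set test). The unfolded protein response had 12 and 7 of 31 (adjusted p = 0.489, with a median of -0.05, a mean of 0.16 and a positive direction). Glycolysis had 7 and 10 of 24 (adjusted p = 0.56, with a median of 0.00, a mean of -0.10 and a negative direction). Heat shock proteins had 10 and 2 of 22 (adjusted over the list alone, 10 and 3; adjusted p = 0.255). Of 7 mitochondrially encoded genes, 1 passed, MT-CO1 (log2 0.50, edgeR adjusted p = 0.00556), and the list was not called (adjusted p = 0.56). MT-CO1 took 3.05% of counts in 12 h replicate 1 and 2.15% and 2.09% in the other 12 h libraries, and without replicate 1 its log2 fold change was 0.29 (edgeR adjusted p = 0.032).

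The comparison of 12 h with 5 h asked what changed between the activated groups. IL2 fell from 260.1 ± 38.1 to 15.1 ± 0.740 CPM (log2 -4.11 ± 0.13 SE, edgeR adjusted p = 3.17e-15, n = 3). CSF2 fell to 3.09 ± 0.304 CPM (log2 -3.96), the chemokine genes CCL3 (5.53 to 0.158 CPM, log2 -4.70), CCL4L2 (log2 -3.37) and CXCL8 (log2 -3.22) fell, and so did TBX21, which encodes the transcription factor T-bet (26.5 to 2.45 CPM, log2 -3.31). The nuclear receptors NR4A1 (log2 -2.84), NR4A2 (26.1 to 1.42 CPM, log2 -4.20) and NR4A3 (635 to 52.4 CPM, log2 -3.60) fell, as did EGR1 (log2 -1.29), EGR2 (log2 -2.17) and CD69 (log2 -1.39). IL2RA was 294 against 339 CPM (log2 -0.20, edgeR adjusted p = 0.0923), and was called lower without 12 h replicate 2 (log2 -0.29, adjusted p = 0.0275). The largest rises were in GPR158 (1.92 to 9.92 CPM, log2 2.32), RAB33A (log2 2.14), the granzyme gene GZMK (2.04 to 9.09 CPM, log2 2.13), WIPI1 (log2 2.09) and the beta-1 adrenergic receptor gene ADRB1 (5.47 to 20.6 CPM, log2 1.92). METTL7A (log2 1.82), TMEFF1 (log2 1.79) and YPEL2 (log2 1.77) followed.

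In all, 2178 genes were higher and 2162 lower at 12 h than at 5 h, 36.1% of those tested by edgeR, with 250 and 270 by at least 2-fold. Camera called 12 of 26 lists, and 5 held with an estimated correlation. Immediate-early factors had 0 higher and 17 lower of 23 (adjusted p = 1.99e-15, and adjusted p = 0.0249 with an estimated correlation). Cytokines and chemokines had 2 and 15 of 19 (adjusted p = 1.63e-11, and adjusted p = 0.034 with an estimated correlation). NF-κB targets had 0 and 13 of 22 (adjusted over the list alone, 1 and 14; adjusted p = 7.62e-08, and adjusted p = 0.0249 with an estimated correlation), among them the inhibitors NFKBIA (161 to 57.0 CPM, log2 -1.49) and NFKBID (log2 -2.31). Negative-feedback regulators had 2 and 17 of 32 (adjusted over the list alone, 2 and 19; adjusted p = 8.49e-07, and adjusted p = 0.0235 with an estimated correlation), with DUSP2 down from 1223 to 317 CPM (log2 -1.95) and SOCS1 from 38.1 to 9.39 CPM (log2 -2.04). Cholesterol synthesis genes had 21 higher and 1 lower of 23, with a median of 0.98 (adjusted p = 5.31e-17, and adjusted p = 0.0235 with an estimated correlation). MVK rose from 7.64 to 22.9 CPM (log2 1.57) and MVD from 15.1 to 41.8 CPM (log2 1.48).

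The other 7 calls between 12 h and 5 h were lost with an estimated correlation. Ribosome biogenesis genes fell, with 2 higher and 38 lower of 56 (adjusted over the list alone, 2 and 39; camera adjusted p = 5.09e-14, but adjusted p = 0.145 with an estimated correlation), among them the helicase gene DDX21 (711 to 354 CPM) and the polymerase I subunit gene POLR1B (149 to 65.4 CPM, log2 -1.18). Mitosis genes rose, with 33 higher and 0 lower of 46 (camera adjusted p = 1.63e-11, but adjusted p = 0.145 with an estimated correlation), including the centromere histone gene CENPA (13.3 to 26.3 CPM, log2 0.97) and PSRC1 (log2 1.18). Ribosomal proteins had 48 higher and 0 lower of 77 (adjusted over the list alone, 57 and 0; camera adjusted p = 1.04e-11, but adjusted p = 0.425 with an estimated correlation). DNA replication genes had 5 higher and 21 lower of 46 (adjusted over the list alone, 5 and 23; camera adjusted p = 0.00558, but adjusted p = 0.399 with an estimated correlation). Unfolded protein response genes had 1 higher and 14 lower of 31 (adjusted over the list alone, 1 and 15; camera adjusted p = 3.19e-04, but adjusted p = 0.425 with an estimated correlation), with HSPA5 down from 1933 to 557 CPM (log2 -1.80). Activation receptors had 3 and 13 of 26 (adjusted over the list alone, 3 and 14; camera adjusted p = 1.77e-04, but adjusted p = 0.399 with an estimated correlation), with ICOS down from 46.0 to 12.8 CPM (log2 -1.87) and CD27 up from 93.3 to 173 CPM (log2 0.89). Translation factors had 7 and 14 of 48 (camera adjusted p = 0.0401, but adjusted p = 0.607 with an estimated correlation). That call was lost without 0 h replicate 2 (adjusted p = 0.0517), 5 h replicate 1 (0.0624) or 12 h replicate 1 (0.165).

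Camera called none of the other 14 lists between 12 h and 5 h (adjusted p from 0.115 to 0.984). Interferon-stimulated genes had 9 higher and 8 lower of 36, amino-acid supply 10 and 5 of 38 (adjusted over the list alone, 11 and 6), with SLC7A5 down from 3234 to 1152 CPM (log2 -1.49), and T-cell receptor genes 6 and 5 of 36. Quiescence genes had 8 and 6 of 28 (adjusted over the list alone, 9 and 7; median 0.05, mean -3.69e-04, positive direction), glycolysis 3 and 7 of 24, and heat shock proteins 8 and 2 of 22 (adjusted over the list alone, 9 and 2). Notch pathway factors had 2 and 4 of 21, inhibitory receptors 2 and 4 of 12 (adjusted over the list alone, 3 and 4), histones 1 and 0 of 6, and mitochondrially encoded genes 0 and 0 of 7.

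**Figure D2:**
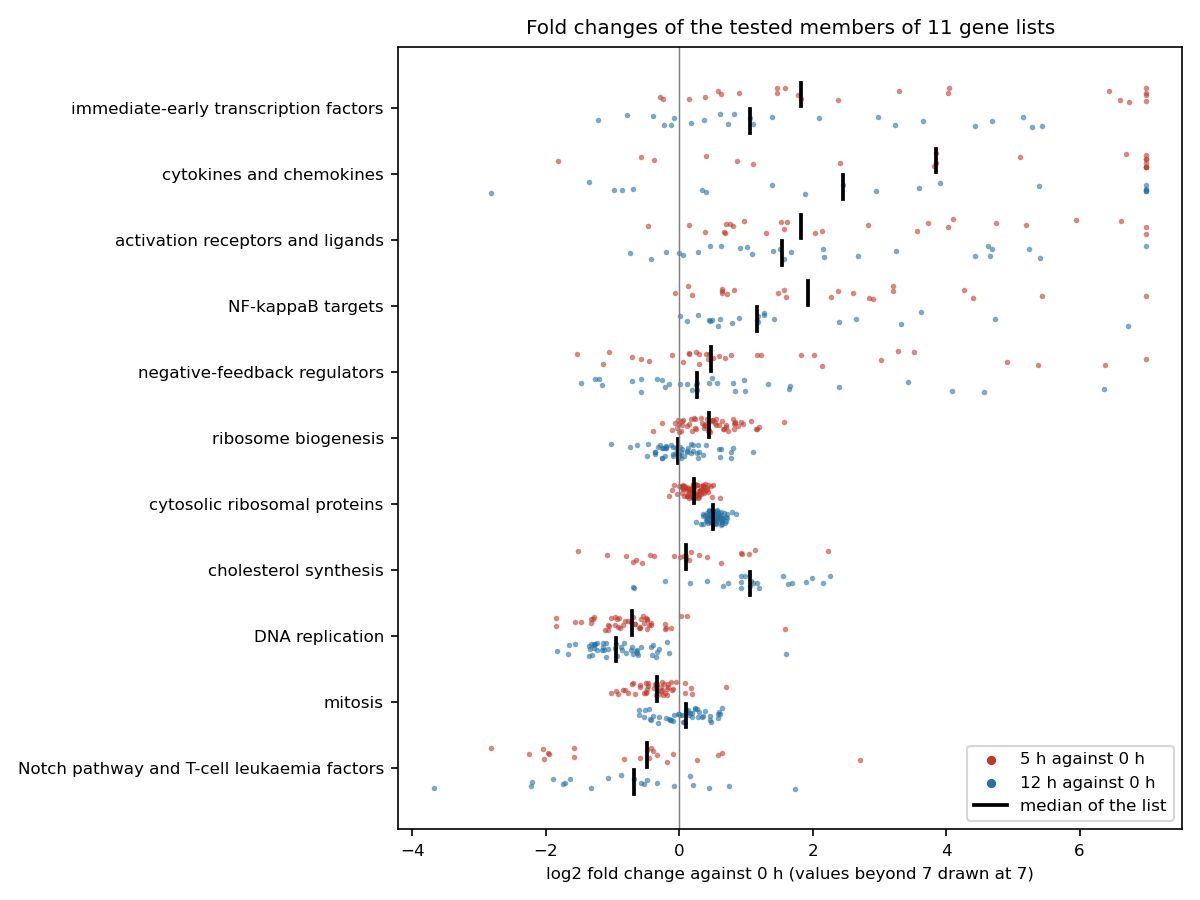
Log2 fold change against 0 h of the tested members of 11 lists at 5 h (red) and 12 h (blue), with the list median as a black line and values beyond 7 drawn at 7. The median of cholesterol synthesis genes was 0.10 at 5 h and 1.06 at 12 h, and that of DNA replication genes -0.71 and -0.95.

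The sets of genes called at 5 h and 12 h against 0 h were then compared. 1957 genes were higher at both times, of which 995 had the smaller change at 12 h, and 1936 were lower at both, of which 971 had the smaller change at 12 h. Lists drawn independently would share 787.9 and 740 genes. A further 941 genes were called higher and 966 lower only at 5 h, and 1121 higher and 946 lower only at 12 h, which does not by itself show that the 2 times differ. 185 genes had opposite calls, 103 higher at 5 h and lower at 12 h and 82 the other way, and all 185 were also called between 12 h and 5 h. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a covariance of 0.636, against 0.025 in 20 simulations of unchanged groups against the same 0 h libraries, a difference of 0.611. Their Pearson r was 0.833 (0.48 in the simulations), the same sign was shared by 75.1% of genes (66.3%), and 3893 genes were called in the same direction (0.1 on average). The covariance difference leaves out what shared controls add. The 3 controls cannot be split into sets of 2, so part of the excess in shared calls and in r may come from the shared controls.

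The miRNA machinery was examined because the study concerns miRNA repression. AGO2, the slicing Argonaute, rose from 171 ± 1.97 to 277 ± 14.1 CPM at 5 h (log2 0.69, edgeR adjusted p = 5.17e-07) and was at 194 ± 3.49 CPM at 12 h (log2 0.18, adjusted p = 0.0743), lower than at 5 h (log2 -0.51, adjusted p = 6.10e-05). DICER1 rose from 144 ± 5.71 to 185 ± 20.9 CPM at 5 h (log2 0.36, adjusted p = 0.00338) and was at 149 ± 11.8 CPM at 12 h (log2 0.05, adjusted p = 0.707). Its call between 12 h and 5 h (log2 -0.32, adjusted p = 0.0138) was lost without 5 h replicate 1 (log2 -0.24) or 12 h replicate 2 (log2 -0.25). DROSHA was at 120.2 ± 4.13, 112 ± 12.5 and 122 ± 3.65 CPM at 0, 5 and 12 h (adjusted p = 0.374 at 5 h and 0.868 at 12 h). Of 25 miRNA biogenesis and Argonaute factors, 9 rose and 5 fell at 5 h (camera adjusted p = 0.426), 8 and 6 at 12 h (0.8), and 3 and 5 between them (adjusted over the list alone, 3 and 4; 0.57). The RNA-editing gene ADAR rose from 580.3 to 946 CPM at 5 h (log2 0.71), the microprocessor gene DGCR8 fell from 117 to 71.2 CPM (log2 -0.72) and the Argonaute partner TNRC6C fell from 166 to 57.3 CPM (log2 -1.54). TNRC6B was at 147, 156 and 308 CPM, with a rise from 5 h to 12 h (log2 0.98).

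Genes that act downstream in mRNA decay also moved both ways. Of 40 deadenylation, decapping and decay factors, 14 rose and 5 fell at 5 h (camera adjusted p = 0.0679), 12 and 8 at 12 h (0.56), and 5 and 11 between them (0.324). The exonuclease gene XRN1 rose from 71.9 to 125 CPM at 5 h (log2 0.80). Of 29 RNA-binding regulators of mRNA stability, 15 rose and 6 fell at 5 h (camera adjusted p = 0.0505), 13 and 8 at 12 h (0.255), and 4 and 10 between them (adjusted over the list alone, 5 and 10; 0.156). ZFP36L1, which promotes decay of AU-rich mRNAs, rose from 40.4 ± 6.74 to 651 ± 21.1 CPM at 5 h (log2 4.01) and its relative ZFP36L2 fell from 128 ± 10.8 to 46.3 ± 1.58 CPM (log2 -1.46). ZC3H12C had 1 count at 0 h and 40 at 5 h, a ratio of 44.5 (7.53 to 1799). Of 14 measured miRNA host genes, 3 rose and 7 fell at 5 h (camera adjusted p = 0.171), 6 and 7 at 12 h (0.719), and 7 and 3 between them (0.373). VMP1, whose locus overlaps the miR-21 region, rose from 110 ± 6.37 to 700.1 ± 50.7 CPM at 5 h (log2 2.67), and SREBF1, which hosts miR-33b, fell from 191 ± 13.3 to 61.7 ± 10.2 CPM (log2 -1.63).

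Transcripts with miRNA sites differed little on average from those without. In limma on the site coefficients, 16, 19 and 14 of 32 families or motifs were called for 5 h against 0 h, 12 h against 0 h and 12 h against 5 h. Genes with a miR-155 site (1434 of 11952) shifted by 0.0143 log2 units at 5 h (adjusted p = 0.0822) and by 0.0596 at 12 h (adjusted p = 2.67e-13). Genes with a let-7 site shifted by 0.0328 and 0.0645, and those with a miR-27 site by 0.0455 at 5 h. The liver miRNA miR-122, included as a control, gave 0.0325 and 0.0677. Genes with an AU-rich element shifted by 0.0688 at 5 h (adjusted p = 2.23e-16), 0.0495 at 12 h and -0.0194 between them. All these limma p-values rest on a spread pooled over families. Of 1080 random 7-mers, 41.7%, 53.1% and 47.4% were called in the same test, and their central 95% ran from -0.0484 to 0.0466 at 5 h, from -0.0362 to 0.0635 at 12 h, and from -0.0132 to 0.0467 between 12 h and 5 h. Of the called miRNA families, 0 of 13, 1 of 16 (let-7) and 0 of 12 lay outside that range.

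**Figure D3:**
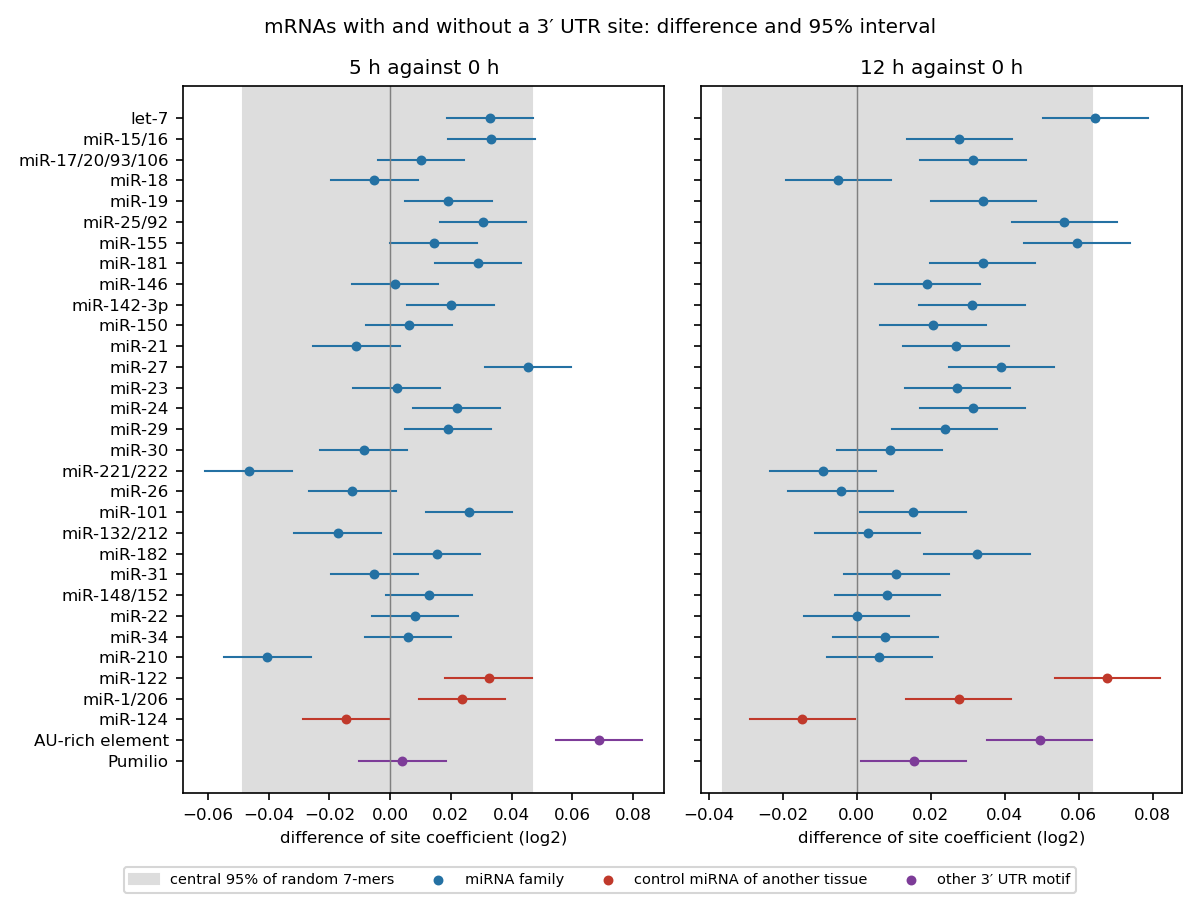
Difference of the site coefficient (log2 units) with its 95% interval for 32 families or motifs, for 5 h against 0 h and 12 h against 0 h. Blue marks miRNA families, red control miRNAs and purple other motifs, and the grey band is the central 95% of 1080 random 7-mers. The intervals rest on a spread pooled over families. Let-7 lay above the band at 12 h (0.0645 against 0.0635), as did the control miR-122 (0.0677). The AU-rich element lay above the band at 5 h (0.0688 against 0.0466). Between 12 h and 5 h, which is not drawn, it lay below the range of the random 7-mers (-0.0194 against -0.0132).

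Markers of other cell types were sparse, with 2 of 11 B-cell, 3 of 12 myeloid and 3 of 13 epithelial or fibroblast markers passing the expression filter, too few for a set test. At 5 h, 0 rose and 1 fell in each of these lists: CD79A (177 to 101 CPM, log2 -0.80), AIF1 (97.3 to 70.0 CPM, log2 -0.47) and THY1 (38.1 to 12.4 CPM, log2 -1.62). At 12 h, 0, 1 and 0 rose and 1, 1 and 1 fell, and between 12 h and 5 h 1, 0 and 0 rose and none fell. The 12 h calls of CD79A and AIF1 were lost without some single libraries, for CD79A without 0 h replicate 3 (log2 -0.20) or 12 h replicate 3 (log2 -0.25). AIF1 lost its call without 0 h replicate 1 (log2 -0.29) or 3 (-0.32), or without 12 h replicate 1 (-0.24) or 3 (-0.33). That of CD68, the myeloid gene called higher at 12 h, was lost without 0 h replicate 1 (log2 0.46) or 12 h replicate 2 (log2 0.61). Mitochondrially encoded genes took 3.77% to 5.88% of counts per library, the highest in 12 h replicate 1, which was also the shallowest.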

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

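The tests of the ribosomal protein list against the spread between libraries and of its share of counts, of the mitosis list, and of the signed median of the seed families were chosen only after the result was seen.

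20 named genes had opposite edgeR calls at 5 h and 12 h against 0 h, and the test of 12 h against 5 h also called each of them. 11 of them rose at 5 h and fell below 0 h at 12 h. Their log2 fold changes from 5 h to 12 h were -1.60 for the growth regulator MYC, -2.60 for FOSL2, -3.68 for IL13, -2.08 for LTA, -1.42 for IL2RB, -1.18 for POLR1B, -0.95 for EIF5, -1.14 for ETF1, -0.84 for CNOT10, -0.87 for DNAJC3 and -0.70 for PFKFB3. IL13 rested on few counts, at 1.87, 3.45 and 0.285 CPM at 0, 5 and 12 h. IL2RB was at 5.54, 8.98 and 3.25 CPM. Their rises at 5 h had edgeR adjusted p-values close to the threshold, 0.0394 for IL13 and 0.0336 for IL2RB. The other 9 fell at 5 h and rose above 0 h at 12 h. These were the chaperone genes HSPA1B (1.45), DNAJB1 (0.76) and CHORDC1 (0.96), the mevalonate enzyme genes MVK (1.57) and MVD (1.48), the mitotic genes PSRC1 (1.18) and CENPA (0.97), the interferon-stimulated gene BST2 (1.16) and the cell-cycle inhibitor gene CDKN1B (0.90). The 12 h call against 0 h was lost for LTA without 0 h replicate 2 (log2 -0.58) or 12 h replicate 3 (-0.82). That of IL2RB was lost without 0 h replicate 2 (log2 -0.77) or 3 (-0.43), without 5 h replicate 2 (-0.74), or without 12 h replicate 1 (-0.68) or 3 (-0.59). It was also lost in the DESeq2 Wald test (log2 -0.74, adjusted p = 0.0579) and in an edgeR fit of only the compared groups (log2 -0.74, adjusted p = 0.0528). The log2 fold change in the main fit was -0.73.

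The edgeR counts were set against other splits of the libraries. With only the compared groups in the fit, the real split called 6364 genes for 5 h against 0 h, 5964 for 12 h against 0 h and 4131 for 12 h against 5 h. The highest of the other splits called 0, 0 and 1. Each of those splits mixed libraries of both times on each side, so the difference between times entered the spread. Their low counts therefore do not measure how many calls arise without a difference. In each comparison 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

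The seed families formed the first pattern weighed. The median absolute difference of the 27 miRNA families was 0.0155 at 5 h and 0.0238 at 12 h. Random sets of 27 matched 7-mers gave 0.0147 and 0.0192, so the families stood at percentiles 58.8 and 82.6, below the 95th percentile of those sets. The size of the shifts is therefore consistent with a background that any 7-mer of a 3′ UTR may share. The signed median at 5 h, 0.0101, stood at percentile 98.9 of the random sets, which goes the other way, and at 12 h it stood at percentile 94.5. A small common rise of miRNA targets at 5 h stays open and was not tested further.

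The rise of all 77 tested ribosomal protein genes at 12 h was the second pattern. The 139 genes outside the list matched on transcript length, GC content and level had a median log2 fold change of -0.001 (95% range -0.095 to 0.105) against 0.51 for the list, which argues against these properties as its source. Fry, which sets the members' common shift against the spread between libraries of a group, gave an adjusted p of 0.00185. This test was chosen after the list results were seen, and its spread is pooled over the groups. The share of counts varied more at 12 h (SD 0.59) than at 0 h (SD 0.16). Fry therefore does not settle whether that spread is the source. The exact permutation p of the share of counts, 0.1, is the smallest that 3 against 3 libraries can reach and decides nothing, and camera with the members' estimated correlation of 0.62 gave an adjusted p of 0.346. Activation for 12 h stays a candidate explanation, which cannot be told apart here from 12 h in culture, and a difference in handling shared by the libraries of a group was not tested.

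The fall of the DNA replication genes at 12 h was the third pattern. The 226 matched genes had a median log2 fold change of 0.017 (95% range -0.108 to 0.128) against -0.95 for the list, which argues against length, GC content and level. If cells of every cycling phase had become fewer, the mitosis list would also be lower. The bound for this, a median of -0.475 or below, was set after the list results were seen. The median was 0.102, so the mitosis list did not fall with the replication list at 12 h. The SD of 0.351 between members does not measure the spread between libraries. At 5 h both lists fell, with medians of -0.34 (mitosis) and -0.705 (replication). No verdict on fewer cycling cells is therefore drawn. Activation for 12 h stays a candidate explanation, which cannot be told apart here from 12 h in culture or handling, and how it would act was not tested.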

How the results depend on the processing

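Apart from the settings named next, the counts of genes called higher or lower, of lists, of families and of genes called in the same direction at both times stayed within 1.5 times their value in the report in each alternative run for them and without each library. These were 7 alternatives for genes, 5 for lists and 3 for families. Which families were called was less stable than their number. With 8mer sites only, 11 of 16 were called again for 5 h against 0 h, 15 of 19 for 12 h against 0 h and 8 of 14 for 12 h against 5 h. The counts by 2-fold and of opposite calls were not run again. Against a fold of 1.5, a stricter question by construction, edgeR called 763 genes higher and 808 lower at 5 h, 824 and 769 at 12 h, 379 in all between 12 h and 5 h (173 higher, 2.1e+02 lower after rounding), and 924 in the same direction at both times. With an estimated correlation, camera called 5, 4 and 5 lists (the cause was not tested), and fry, which asks another question, called 21 at 5 h. Leaving out 1 library at a time gave 2592 to 3131 higher and 2542 to 3175 lower genes at 5 h, 2843 to 3196 and 2674 to 3089 at 12 h, and 1638 to 2262 and 1646 to 2176 between them. Of 328 called results for named genes, 27 lost their call under at least 1 of the other alternatives or left-out libraries, and 118 did so against a fold of 1.5. The sign of uncalled values near 0 turned for DROSHA at 12 h without 0 h replicate 3 (log2 -0.0052) and, without 12 h replicate 1, for DICER1 (-0.0070) and DROSHA (-0.0080). Over the left-out libraries DICER1 ran from -0.0070 to 0.111 and DROSHA from -0.0080 to 0.049.

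The groups share replicate numbers, but libraries of the same number had correlations of their deviations from -0.215 to 0.335. By the rule fixed beforehand, over 0.1 in every pair, they were not treated as paired. Same-numbered 5 h and 12 h libraries had positive correlations (0.335, 0.307 and 0.065), so a link between these groups is not excluded. Not every library correlated best with its own number, and 0 h replicate 2 went with 5 h replicate 1 (0.214). With the replicate block, edgeR called 2989 and 2992 genes at 5 h, 3149 and 3027 at 12 h, 2156 and 2129 between them and 3896 in the same direction, camera called 13, 11 and 12 lists, and limma 15, 19 and 11 families. Depth limits genes with few counts, since a count of 0 over the 0 h group allows up to 0.132 CPM.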

Other observations

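The groups in the next paragraph were chosen after the data were seen: after a trial of hand-picked symbol stems, all 198 stems shared by at least 8 tested genes were run through camera. It called 8, 2 and 5 of them for 5 h against 0 h, 12 h against 0 h and 12 h against 5 h, and none held with an estimated correlation.

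Of 11 tested HLA genes, 6 were higher and 0 lower at 5 h and at 12 h (camera adjusted p = 0.0483 and 0.0327, but adjusted p = 0.769 and 0.946 with an estimated correlation). HLA-DMA, HLA-DOA, HLA-DOB and HLA-G were not called at either time. HLA-B went from 425 CPM at 0 h to 1014 at 5 h and 1422 at 12 h, and HLA-E from 189.7 to 618 and 719. The light chain gene B2M and the peptide transporter gene TAP1 were picked by hand. B2M went from 1988 ± 255 to 2905 ± 171 and 3556 ± 121 CPM (SD, n = 3) and TAP1 from 105 to 411 and 374. HLA genes are similar and polymorphic, and the assignment of their reads was not tested. Of 10 genes whose symbol starts with IRF, which are 7 interferon regulatory factors and 3 IRF2-binding protein genes, 7 were higher and 0 lower at 5 h (camera adjusted p = 0.00429, but adjusted p = 0.739 with an estimated correlation), with IRF8 at 6.31, 43.8 and 20.5 CPM at 0, 5 and 12 h and IRF9 at 49.9 CPM at 5 h and 48.7 CPM at 12 h. Of 20 ZDHHC palmitoyltransferase genes, 1 was higher and 12 lower at 5 h (camera adjusted p = 0.0368, but adjusted p = 0.769 with an estimated correlation), among them ZDHHC2 (54.0 to 25.1 CPM). The ZDHHC genes were not called at 12 h (2 higher and 12 lower, camera adjusted p = 0.117) or between 12 h and 5 h (4 and 4, 0.94).

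Other single genes, chosen after their values were seen, moved apart with time. EOMES, a T-box factor, was at 6.88, 126 and 126 CPM at 0, 5 and 12 h, while its relative TBX21 was at 0.804, 26.5 and 2.45 CPM. PER2, a circadian clock gene, was at 45.8, 68.1 and 21.4 CPM. The phosphatase gene INPP5D was at 51.7, 36.0 and 90.1 CPM and the desaturase gene SCD at 1238, 858 and 1730 CPM.

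The deposited log2 table lists only genes with a count in all 9 libraries, so it leaves out genes silent in 1 group. Of the 20 called genes with the highest fold change, it leaves out 16 at 5 h and 15 at 12 h, IL2RA among them at both times, and 7 between 12 h and 5 h. Of all called genes it leaves out 92, 85 and 44.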
